A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

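Gene expression was measured in 12 cultures of Saccharomyces cerevisiae S288C on Affymetrix arrays with 9335 probe sets. Per the labels, cultures were diluted to an OD600 of 0.1, grown for 1 h at 30 °C, given the compound or the solvent dimethylformamide, and grown for 5 h more, on 3 independent days. Groups and doses were taken from the sample titles. Another label field names 15 uM tomatidine for every sample, controls included, and was not used.

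The deposited values are probe set intensities that the authors made with RMA; the labels give no version or settings. They were on a linear scale, with values from 1.84 to 21252 and array medians of 77.2 to 78.6. The analysis had been planned for log2 values, so log2 of each value was taken. The 60 control probe sets were left out and 9275 were tested. Of these, 6504 name 1 gene, 328 name several and 2443 name none in the platform annotation. All 6504 were matched to the S288C reference table (assembly R64), and 0 symbols needed updating. For gene lists and gene names the probe set with the highest mean signal stood for each of 5656 genes.

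One linear model with the 4 groups was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), with moderated variances (prior degrees of freedom 3.65, residual 8). Each compound was compared with control and with each other compound. Tests were two-sided, p-values were Benjamini-Hochberg adjusted over the 9275 probe sets, and an adjusted p under 0.05 was called. A test of any difference among the groups used the moderated F statistic. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

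Before the data were examined, 35 gene lists of pathways, stress responses and mating types were written, with 810 entries, of which 775 were measured. Each list was tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with p-values adjusted over the 35 lists of a comparison. The directional test fry was run beside it. Members of a list were counted when called over all probe sets and also when adjusted over the list alone.

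The genes to name were chosen by a rule written before the data were examined. For each compound against control it took the 10 highest and the 10 lowest log2 fold changes among called probe sets that name exactly 1 gene and moved the same way on all 3 days. For each pair of compounds it took 5 and 5. It added the members of the late ergosterol and the mevalonate lists against control, the 4 members with the largest change of each other called list, and ERG2, ERG24, ERG6, ERG4, ERG3, ERG5, ERG11, ERG25, HMG1, UPC2 and PDR5 in every comparison.

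Replicate numbers stand for the shared day of culture and pair the samples. This was checked on the deviations from the group means: arrays of the same day had a mean correlation of 0.0351 (18 pairs, -0.203 to 0.236), and 31 of the 216 possible pairings of the days gave a mean as high (exact permutation test, one-sided p = 0.144). The model used for the results had no term for day, as planned before the data were examined, and the day was added as a block in an alternative. Arrays within a group correlated at 0.995 to 0.997 and arrays of different groups at 0.975 to 0.996.

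Alternatives planned before the data were examined were a day block, quantile normalization, median centring, array weights, a trended robust prior, unmoderated statistics, only bright probe sets, 1 probe set per gene or the mean of a gene's probe sets, only the 2 compared groups in the fit, a change of at least 2-fold, other set tests, and leaving out each array. Adding 16 before the log and leaving out probe sets marked for cross-hybridisation were chosen after the values were seen. The method was tested on simulated data with 9275 probe sets: it called 88.1% to 94.0% of 1.5-fold changes, 95.5% to 97.0% of 2-fold changes and all 4-fold changes, with 8 false calls of 197, 9 of 203 and 15 of 207 in the 3 comparisons with control. In the simulated lists the shifted list was called and 0 of 34 others were. The simulated genes varied independently, so this could not test the list calls where genes vary together.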

Results

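RNA from 12 cultures of Saccharomyces cerevisiae S288C was measured on Affymetrix arrays, 1 array per culture. The 4 groups of 3 arrays received the solvent dimethylformamide (control), tomatidine at 0.625 ppm, tomatine at 13.9 ppm or fenpropimorph at 0.313 ppm, for 5 h. Tomatine is a steroidal glycoalkaloid of tomato and tomatidine is its aglycone, the same steroid without the sugars. Fenpropimorph is a morpholine fungicide that blocks the sterol reductase ERG24 and the sterol isomerase ERG2. The doses and compounds are those of the sample titles; another field of the labels names tomatidine for every sample, controls included. Each of the 3 days of culture gave 1 array per group, and an array is named below by its group and day (control 2 is the control of day 2). The median signal was 77.2 to 78.6 per array, and the number of arrays limits the precision. Values after ± are standard errors with n = 3 arrays in each group, and every named gene that rose or fell did so on each of the 3 days. The 95% intervals are not adjusted for the number of tests, and p-values measure the spread between cultures of the 3 days.

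Across the 4 groups, 3446 of 9275 tested probe sets differed (limma, Benjamini-Hochberg adjusted). The first principal component held 59.8% of the variance and set the 3 fenpropimorph arrays apart from the other 9, and the second held 10.1%. Against control, 412 probe sets changed with tomatidine (235 higher, 177 lower), 404 with tomatine (240 higher, 164 lower) and 2808 with fenpropimorph (1239 higher, 1569 lower). Changes of at least 2-fold were 53 with tomatidine (45 higher, 8 lower), 13 with tomatine (4 higher, 9 lower) and 335 with fenpropimorph (278 higher, 57 lower), so that for tomatine and fenpropimorph the balance of directions was the opposite. No probe set differed between days (0 by limma, 579 at an unadjusted p under 0.05).

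The comparison of tomatidine with control asks how yeast cells respond to the aglycone. All 14 measured genes of late ergosterol synthesis, which turn squalene into ergosterol, rose with tomatidine (14 adjusted over the list alone). Across the full list the median log2 fold change was 0.75 (camera adjusted p = 3.14e-25, adjusted p = 0.0171 with an estimated correlation). ERG28, a scaffold of the sterol demethylation enzymes, rose 2.32-fold (log2 fold change 1.21 ± 0.096, adjusted p = 2.48e-05), and ERG3, the sterol C-5 desaturase, rose 2.22-fold (log2 fold change 1.15 ± 0.0626, adjusted p = 1.92e-06). The genes of the fenpropimorph targets ERG24 and ERG2 rose 1.92-fold and 1.76-fold (log2 fold changes 0.94 ± 0.148 and 0.82 ± 0.0707, adjusted p = 0.00306 and 4.5e-05). ERG5 and ERG4, which act at the end of the pathway, rose by 0.86 ± 0.0729 and 0.75 ± 0.0618 on the log2 scale, and ERG6, the sterol methyltransferase, by 0.68 ± 0.137. The smallest rise of the list was that of ERG11, lanosterol demethylase (log2 fold change 0.45 ± 0.0671, adjusted p = 0.00242). The sterol-sensing transcription factor UPC2 rose 1.73-fold (log2 fold change 0.79 ± 0.142, adjusted p = 0.00786). The call of ERG1 was lost without tomatidine 2 (adjusted p = 0.0663) and control 3 (adjusted p = 0.0543), and that of ERG6 was lost without tomatidine 1 (adjusted p = 0.0644), control 1 (adjusted p = 0.0545), tomatidine 2 (adjusted p = 0.0598) and control 3 (adjusted p = 0.0529).

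Earlier in the pathway, 1 of 10 genes of the mevalonate and farnesyl steps rose (2 adjusted over the list alone). For the whole list the median log2 fold change was 0.15 (camera adjusted p = 0.00597, adjusted p = 0.119 with an estimated correlation). The gene that rose was ERG9, squalene synthase (log2 fold change 0.60 ± 0.0918, adjusted p = 0.00276). HMG1, the hydroxymethylglutaryl-CoA reductase, had a log2 fold change of 0.16 (95% interval -0.01 to 0.32, adjusted p = 0.316).

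DAN1 and DAN4, cell wall mannoproteins of anaerobic growth, were the 2 highest genes, and their relatives TIR4 and TIR3 were among the 10 highest. DAN1 rose 33.9-fold (log2 fold change 5.08 ± 0.344, adjusted p = 8.95e-06), and DAN4, TIR4 and TIR3 rose 10.5-fold, 4.86-fold and 4.1-fold (log2 fold changes 3.39 ± 0.196, 2.28 ± 0.179 and 2.04 ± 0.112). HES1, a homologue of oxysterol-binding proteins, rose 9.04-fold (log2 fold change 3.18 ± 0.215, adjusted p = 8.95e-06), and ATF2, an alcohol acetyltransferase that also acts on steroids, rose 3.75-fold (log2 fold change 1.91 ± 0.0752, adjusted p = 1.38e-07). PBI1, YMR317W, YSR3 and SET4 completed the 10 highest, with log2 fold changes of 2.58 ± 0.18, 2.55 ± 0.188, 2.02 ± 0.175 and 1.85 ± 0.277. Of the 23 genes of sterol uptake, storage and the anaerobic cell wall, 13 rose (14 higher and 2 lower adjusted over the list alone). Over all its members the list had a median log2 fold change of 0.51 (camera adjusted p = 3.65e-13, adjusted p = 0.0338 with an estimated correlation).

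Of the 18 genes of the phosphate regulon, 11 rose (15 higher and 1 lower adjusted over the list alone). At the list level the median log2 fold change was 0.32 (camera adjusted p = 4.37e-13, adjusted p = 0.0875 with an estimated correlation). The phosphate transporter PHO89 rose 3.4-fold and the acid phosphatase PHO5 2.43-fold (log2 fold changes 1.77 ± 0.168 and 1.28 ± 0.113). Of 25 genes of methionine synthesis and sulfate assimilation, 10 rose (10 adjusted over the list alone). The median log2 fold change of the whole list was 0.34 (camera adjusted p = 3.91e-11, adjusted p = 0.119 with an estimated correlation). MET2, MET17 and MET14 rose by 1.23 ± 0.185, 1.09 ± 0.0979 and 0.87 ± 0.102 on the log2 scale. Among 39 genes of amino acid synthesis under GCN4 control, 23 rose (30 adjusted over the list alone). Across the full list the median log2 fold change was 0.32 (camera adjusted p = 6.18e-20, adjusted p = 0.114 with an estimated correlation). The genes that rose included ARG4, of arginine synthesis (log2 fold change 1.02 ± 0.113, adjusted p = 0.000248), and HOM3, aspartate kinase (log2 fold change 0.72 ± 0.0715, adjusted p = 0.00011). The count of 23 higher genes in the GCN4-regulated amino acid synthesis list was 9 without tomatidine 1, 12 without control 2, 14 without tomatidine 3 and 14 without control 3.

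Genes of respiration fell with tomatidine. Of 32 genes of the respiratory chain and ATP synthase, 18 fell (30 adjusted over the list alone). For the whole list the median log2 fold change was -0.39 (camera adjusted p = 1.18e-22, adjusted p = 0.114 with an estimated correlation). CYC1, which encodes cytochrome c, was 2.77-fold lower (log2 fold change -1.47 ± 0.157, adjusted p = 0.000195), CYT1, cytochrome c1, was 2.27-fold lower (log2 fold change -1.18 ± 0.149, adjusted p = 0.00069), and the external NADH dehydrogenase NDE1 was 2.19-fold lower (log2 fold change -1.13 ± 0.167, adjusted p = 0.00221). INH1, an inhibitor of ATP synthase, and COA2, an assembly factor of cytochrome oxidase, had log2 fold changes of -0.95 ± 0.0977 and -0.94 ± 0.147. The other lowest genes included ARO10, phenylpyruvate decarboxylase (-1.52 ± 0.167), the stress gene DDR2 (-1.04 ± 0.172) and the polyamine transporter TPO2 (-1.93 ± 0.387). The call of TPO2 was lost without control 1 (adjusted p = 0.0648) and tomatidine 2 (adjusted p = 0.0566). The count of 18 lower genes in the respiratory chain and ATP synthase list was 11 without control 1 and 10 without tomatidine 2.

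Of the 4 genes specific to alpha cells, the mating type of the strain, 2 fell (4 adjusted over the list alone; median log2 fold change -0.48, camera adjusted p = 0.000213, adjusted p = 0.175 with an estimated correlation): the pheromone gene MF(ALPHA)2 (-0.75 ± 0.11) and the agglutinin gene SAG1 (-0.69 ± 0.118). Among 21 genes of pheromone response and mating, 4 fell and 1 rose (8 and 1 adjusted over the list alone). Over all its members the list had a median log2 fold change of -0.18 (camera adjusted p = 0.000151, adjusted p = 0.119 with an estimated correlation). The 5′ probe set of the array's control gene SPT15 was higher with tomatidine (log2 fold change 0.36, SE 0.0841, adjusted p = 0.0346), with a 3′ to 5′ log2 ratio of 1.82 ± 0.285 (SD, n = 3) against 2.33 ± 0.174 in control; for ACT1 the ratios were 0.46 ± 0.128 and 0.35 ± 0.0244. By camera, 9 lists stood higher and 7 lower than other genes, and 2 of these calls held with an estimated correlation. The count of 412 probe sets was 260 without tomatidine 1, 245 without control 1, 221 without tomatidine 2, 273 without control 2 and 252 with only these 2 groups in the fit.

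**Figure D1:**
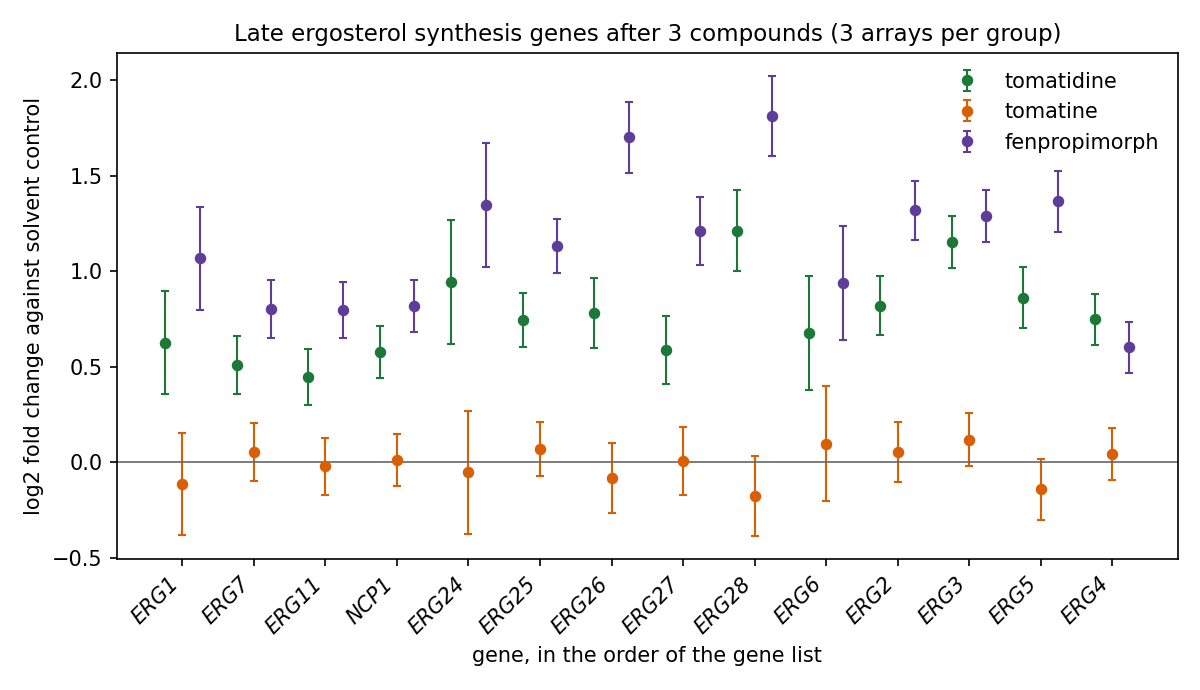
Log2 fold change against solvent control of the 14 late ergosterol genes after tomatidine, tomatine and fenpropimorph (points; bars are 95% intervals, 3 arrays per group). Tomatidine and fenpropimorph lie above 0 for all 14 genes and every tomatine interval includes 0.

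The comparison of tomatine with control asks the same of the glycoalkaloid. The lowest gene was GCV2, a subunit of glycine decarboxylase, at 2.92-fold lower than control (log2 fold change -1.54 ± 0.216, adjusted p = 0.00597), and the subunit genes GCV1 and GCV3 also fell (log2 fold changes -1.13 ± 0.132 and -0.83 ± 0.113, adjusted p = 0.00436 and 0.00574). MTD1, a dehydrogenase of one-carbon metabolism, fell as well (log2 fold change -0.99 ± 0.153, adjusted p = 0.00801). Of 20 genes of purine synthesis and one-carbon metabolism, 12 fell and 1 rose (12 and 1 adjusted over the list alone). At the list level the median log2 fold change was -0.50 (camera adjusted p = 3.28e-09, adjusted p = 0.486 with an estimated correlation). CHA1, which breaks down serine and threonine, rose 2.37-fold (log2 fold change 1.24 ± 0.134, adjusted p = 0.00436). The count of 1 higher gene in the purine synthesis and one-carbon metabolism list was 0 without tomatine 1, 0 without control 1, 0 without tomatine 2, 0 without control 2, 0 without tomatine 3 and 0 without control 3. The count of 12 lower genes in the purine synthesis and one-carbon metabolism list was 6 without control 1, 7 without tomatine 2, 6 without control 2, 6 without tomatine 3 and 6 without control 3. Camera also called this list with tomatidine against control in 5 of 6 fits without 1 array (adjusted p from 8.38e-07 to 0.0547). In those 6 fits 0 to 2 of its genes were lower and 0 higher with tomatidine. All compounds were compared with the same control arrays, and what these add to the list calls was not tested.

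The stress genes HSP26 and HSP12 were 2.33-fold and 2.25-fold lower with tomatine (log2 fold changes -1.22 ± 0.195 and -1.17 ± 0.193, adjusted p = 0.00978 and 0.0112). The general stress list had 13 of 37 genes lower (19 adjusted over the list alone). The median log2 fold change of the whole list was -0.31 (camera adjusted p = 3.76e-12, adjusted p = 0.402 with an estimated correlation). Ribosome biogenesis moved the other way, with 27 of 46 genes higher (45 adjusted over the list alone). Across the full list the median log2 fold change was 0.37 (camera adjusted p = 1.4e-24, adjusted p = 0.263 with an estimated correlation). KRR1, needed to make the small ribosomal subunit, rose 1.43-fold (log2 fold change 0.51 ± 0.0719, adjusted p = 0.00597). Among 32 genes of the respiratory chain and ATP synthase, 5 fell (13 adjusted over the list alone). For the whole list the median log2 fold change was -0.23 (camera adjusted p = 8.79e-11, adjusted p = 0.486 with an estimated correlation). This list was lower with tomatidine and with fenpropimorph too, and all 3 compounds were compared with the same control arrays. The count of 13 lower genes in the general stress response list was 5 without tomatine 1, 3 without control 1, 4 without tomatine 2, 4 without control 2 and 3 without tomatine 3. The count of 27 higher genes in the ribosome biogenesis list was 12 without tomatine 1, 5 without control 1, 14 without tomatine 2, 3 without control 2 and 5 without tomatine 3. The count of 5 lower genes in the respiratory chain and ATP synthase list was 1 without tomatine 1, 0 without control 1, 0 without tomatine 2, 3 without control 2 and 0 without tomatine 3. The ribosome biogenesis and general stress lists were also called by camera with tomatidine against control in every fit without 1 array. The adjusted p ranged from 2.98e-09 to 7.86e-06 and from 7.89e-10 to 2.36e-05. With all arrays, 1 ribosome biogenesis gene was higher and 6 general stress genes were lower with tomatidine. Neither of these list calls held with an estimated correlation.

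Other genes at the ends of the tomatine ranking were the oligopeptide transporter OPT2 (-1.05 ± 0.133) and STF1, a regulator of ATP synthase (-0.9996 ± 0.0783), among the lowest, and FCY21, related to cytosine permeases (0.93 ± 0.117), among the highest. PRM7, a gene named for its pheromone regulation, was the highest, at 2.59-fold (log2 fold change 1.37 ± 0.172, adjusted p = 0.00436). RGI1, PGM2, MUP3 and TDH1 completed the 10 lowest (log2 fold changes -1.16, -1.08, -0.9967 and -0.99), and BSC1, TOD6, DLD3, YOR302W, MXR1, CPA1 and DRS1 the 10 highest (0.90, 0.69, 0.69, 0.64, 0.62, 0.61 and 0.60). Of the 36 called genes that the naming rule took for this comparison, 11 lost their call without tomatine 1, 20 without control 1, 18 without tomatine 2, 17 without control 2, 22 without tomatine 3 and 7 without control 3, and GCV2, GCV1, GCV3, HSP26, HSP12, CHA1, KRR1, OPT2, STF1, FCY21 and PRM7 kept theirs without any 1 array.

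None of the ergosterol genes passed the test with tomatine. In the late ergosterol list limma called 0 of 14 (0 adjusted over the list alone; 0 at an unadjusted p under 0.05; median log2 fold change 0.01, camera adjusted p = 0.928), and in the mevalonate and farnesyl list 0 of 10 (0 adjusted over the list alone; 0 at an unadjusted p under 0.05; camera adjusted p = 0.987). The 95% intervals were -0.02 to 0.26 for ERG3, -0.10 to 0.21 for ERG2 and -0.38 to 0.27 for ERG24. UPC2 had a log2 fold change of 0.30 (95% interval -0.01 to 0.61, adjusted p = 0.287). By camera, 3 lists stood higher and 6 lower than other genes, and none of these calls held with an estimated correlation. The count of 404 probe sets was 217 without tomatine 1, 83 without control 1, 183 without tomatine 2, 99 without control 2, 100 without tomatine 3 and 121 with only these 2 groups in the fit. It was 625 with 16 added to each value before the log and 645 with 1 probe set per gene. More probe sets were lower than higher with only these 2 groups in the fit (56 higher, 65 lower), without control 2 and without tomatine 3.

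Fenpropimorph, whose targets in sterol synthesis are known, gave the reference response. All 14 late ergosterol genes rose (14 adjusted over the list alone). Over all its members the list had a median log2 fold change of 1.17 (camera adjusted p = 1.39e-13, adjusted p = 0.0686 with an estimated correlation). The target genes ERG24 and ERG2 rose 2.54-fold and 2.5-fold (log2 fold changes 1.35 ± 0.148 and 1.32 ± 0.0707, adjusted p = 2.86e-05 and 6.81e-08). The range ran from ERG4 (0.60 ± 0.0618) to ERG28 (1.81 ± 0.096), with ERG26, ERG5, ERG3, ERG25, ERG6 and ERG11 at 1.70, 1.37, 1.29, 1.13, 0.94 and 0.80. In the mevalonate and farnesyl steps, 8 of 10 genes rose and 1 fell (8 and 1 adjusted over the list alone). At the list level the median log2 fold change was 0.45 (camera adjusted p = 0.000522, adjusted p = 0.0882 with an estimated correlation). ERG9 rose 2.21-fold (log2 fold change 1.14 ± 0.0918, adjusted p = 2.07e-06), and IDI1, which isomerises isopentenyl diphosphate, fell (log2 fold change -0.31 ± 0.0809, adjusted p = 0.0129). UPC2 rose 4.62-fold (log2 fold change 2.21 ± 0.142, adjusted p = 3.15e-07). The call of IDI1 was lost without fenpropimorph 2 (adjusted p = 0.0603). The count of 1 lower gene in the mevalonate and farnesyl steps list was 0 without fenpropimorph 2.

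DAN1 had the largest rise, 76-fold (log2 fold change 6.25 ± 0.344, adjusted p = 8.15e-08), followed by YPR145C-A (5.78 ± 0.322), HES1 (5.12 ± 0.215) and DAN4 (5.04 ± 0.196). TIR4 rose 20.7-fold and RTA1, named for resistance to aminocholesterol, 20.4-fold (log2 fold changes 4.37 ± 0.179 and 4.35 ± 0.0976). PBI1, YMR317W, FHN1 and YPL088W completed the 10 highest (4.86, 4.58, 4.31 and 3.95). Of 23 genes of sterol uptake, storage and the anaerobic cell wall, 16 rose and 3 fell (16 and 4 adjusted over the list alone). The median log2 fold change of the whole list was 1.07 (camera adjusted p = 3.05e-09, adjusted p = 0.0686 with an estimated correlation).

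Drug and stress responses rose with fenpropimorph. Of 20 targets of the regulators PDR1 and PDR3, 15 rose and 4 fell (15 and 4 adjusted over the list alone; median log2 fold change 0.99, camera adjusted p = 1.66e-07, adjusted p = 0.0686 with an estimated correlation), among them GRE2 (2.42 ± 0.11) and the transporter PDR15 (2.07 ± 0.105). The transporter gene PDR5 was not called in any comparison; its log2 fold change here was -0.15 (95% interval -0.50 to 0.20), and its 7 probe sets had mean signals of at most 20.7, under the lower quartile of 21.9. Of 25 genes of cell wall integrity, 15 rose and 3 fell (15 and 4 adjusted over the list alone). Across the full list the median log2 fold change was 0.41 (camera adjusted p = 4.49e-06, adjusted p = 0.131 with an estimated correlation). GSC2, a glucan synthase subunit, rose 7.89-fold (log2 fold change 2.98 ± 0.118, adjusted p = 1.05e-08) and the yapsin genes YPS1 and YPS3 rose by 1.95 ± 0.0868 and 1.79 ± 0.0829 on the log2 scale. Of 37 general stress genes, 27 rose and 1 fell (29 and 1 adjusted over the list alone). For the whole list the median log2 fold change was 0.81 (camera adjusted p = 6.61e-12, adjusted p = 0.152 with an estimated correlation). HSP12 rose 3.92-fold (log2 fold change 1.97 ± 0.193, adjusted p = 1.11e-05). The count of 4 lower genes in the pleiotropic drug resistance list was 2 without fenpropimorph 2 and 2 without control 3. The count of 1 lower gene in the general stress response list was 0 without control 1, 0 without fenpropimorph 2, 0 without control 2 and 0 without fenpropimorph 3.

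Of 25 methionine and sulfate genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone; median log2 fold change 0.68, camera adjusted p = 1.73e-09, adjusted p = 0.145 with an estimated correlation), with MET14 and MET3, of sulfate assimilation, at 2.60 ± 0.102 and 2.35 ± 0.0947. Of 34 proteasome genes, 30 rose (30 adjusted over the list alone; median log2 fold change 0.31, camera adjusted p = 1.1e-10, adjusted p = 0.125 with an estimated correlation), and so did RPN4, their transcription factor (log2 fold change 1.04 ± 0.0902, adjusted p = 3.88e-06). The list of osmotic response and ion homeostasis had 7 of 19 genes higher and 2 lower (8 and 2 adjusted over the list alone). Over all its members the list had a median log2 fold change of 0.14 (camera adjusted p = 0.0107, adjusted p = 0.0882 with an estimated correlation). The calcium-linked genes CMK2, RCN1 and PMC1 were among the higher ones (2.44 ± 0.13, 1.41 ± 0.0998 and 0.97 ± 0.0935). Among the targets of YAP1, 7 of 24 rose and 1 fell (7 and 1 adjusted over the list alone; median log2 fold change 0.11, camera adjusted p = 0.028, adjusted p = 0.198 with an estimated correlation), with the peroxiredoxin gene TSA2 at 15.4-fold. The count of 2 lower genes in the methionine and sulfate assimilation list was 0 without fenpropimorph 2 and 1 without control 3.

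The genes that fell included WSC4 (-2.42 ± 0.226), the hexose transporters HXT7 (-2.14 ± 0.183) and HXT4 (-2.02 ± 0.302), the fatty acid elongase ELO1 (-1.86 ± 0.117), TPO2 (-2.07 ± 0.387), TIP1 (-1.81 ± 0.111) and NDE1 (-2.07 ± 0.167). Of 32 genes of the respiratory chain and ATP synthase, 26 fell (28 adjusted over the list alone; median log2 fold change -0.59, camera adjusted p = 1.66e-09, adjusted p = 0.214 with an estimated correlation), with CYC1 3.61-fold lower (log2 fold change -1.85 ± 0.157, adjusted p = 3.13e-06). Of 20 purine and one-carbon genes, 17 fell (18 adjusted over the list alone; median log2 fold change -0.65, camera adjusted p = 3.44e-06, adjusted p = 0.279 with an estimated correlation), GCV2 among them (-1.06 ± 0.216). Of 46 ribosome biogenesis genes, 34 fell (40 adjusted over the list alone). At the list level the median log2 fold change was -0.30 (camera adjusted p = 7.81e-08, adjusted p = 0.27 with an estimated correlation). Of the array's 60 control probe sets, 9 were lower with fenpropimorph and 0 were higher (limma, with 0 higher and 15 lower at an unadjusted p under 0.05). The lower ones were ribosomal RNA probe sets, those of SPT15 (log2 fold changes -0.27, -0.28 and -0.39), RIP1 (-0.70) and BioDn-3_st (-0.27). The count of 34 lower genes in the ribosome biogenesis list was 22 without control 1, 16 without fenpropimorph 2 and 20 without control 3.

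Mating genes fell with fenpropimorph. All 4 genes specific to alpha cells fell (4 adjusted over the list alone; median log2 fold change -1.55, camera adjusted p = 0.000104, adjusted p = 0.152 with an estimated correlation): MF(ALPHA)2 (-2.09 ± 0.11), SAG1 (-2.02 ± 0.118), the receptor gene STE3 (-1.07 ± 0.0801) and MF(ALPHA)1 (-0.60 ± 0.0664). Of 21 genes of pheromone response and mating, 16 fell and 1 rose (17 and 1 adjusted over the list alone). The median log2 fold change of the whole list was -0.55 (camera adjusted p = 3.33e-06, adjusted p = 0.0882 with an estimated correlation). FUS1, a gene of cell fusion, and SST2, a regulator of pheromone signalling, were 2.4-fold and 2.47-fold lower (-1.26 ± 0.0989 and -1.30 ± 0.0991). In the list of genes specific to a cells, 1 of 7 was called by limma, as higher (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; median log2 fold change -0.03, camera adjusted p = 0.803). By camera, 11 lists stood higher and 7 lower than other genes, and none of these calls held with an estimated correlation. The count of 1 higher gene in the a-mating-type-specific genes list was 0 without control 1, 0 without fenpropimorph 2, 0 without fenpropimorph 3 and 0 without control 3.

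**Figure D2:**
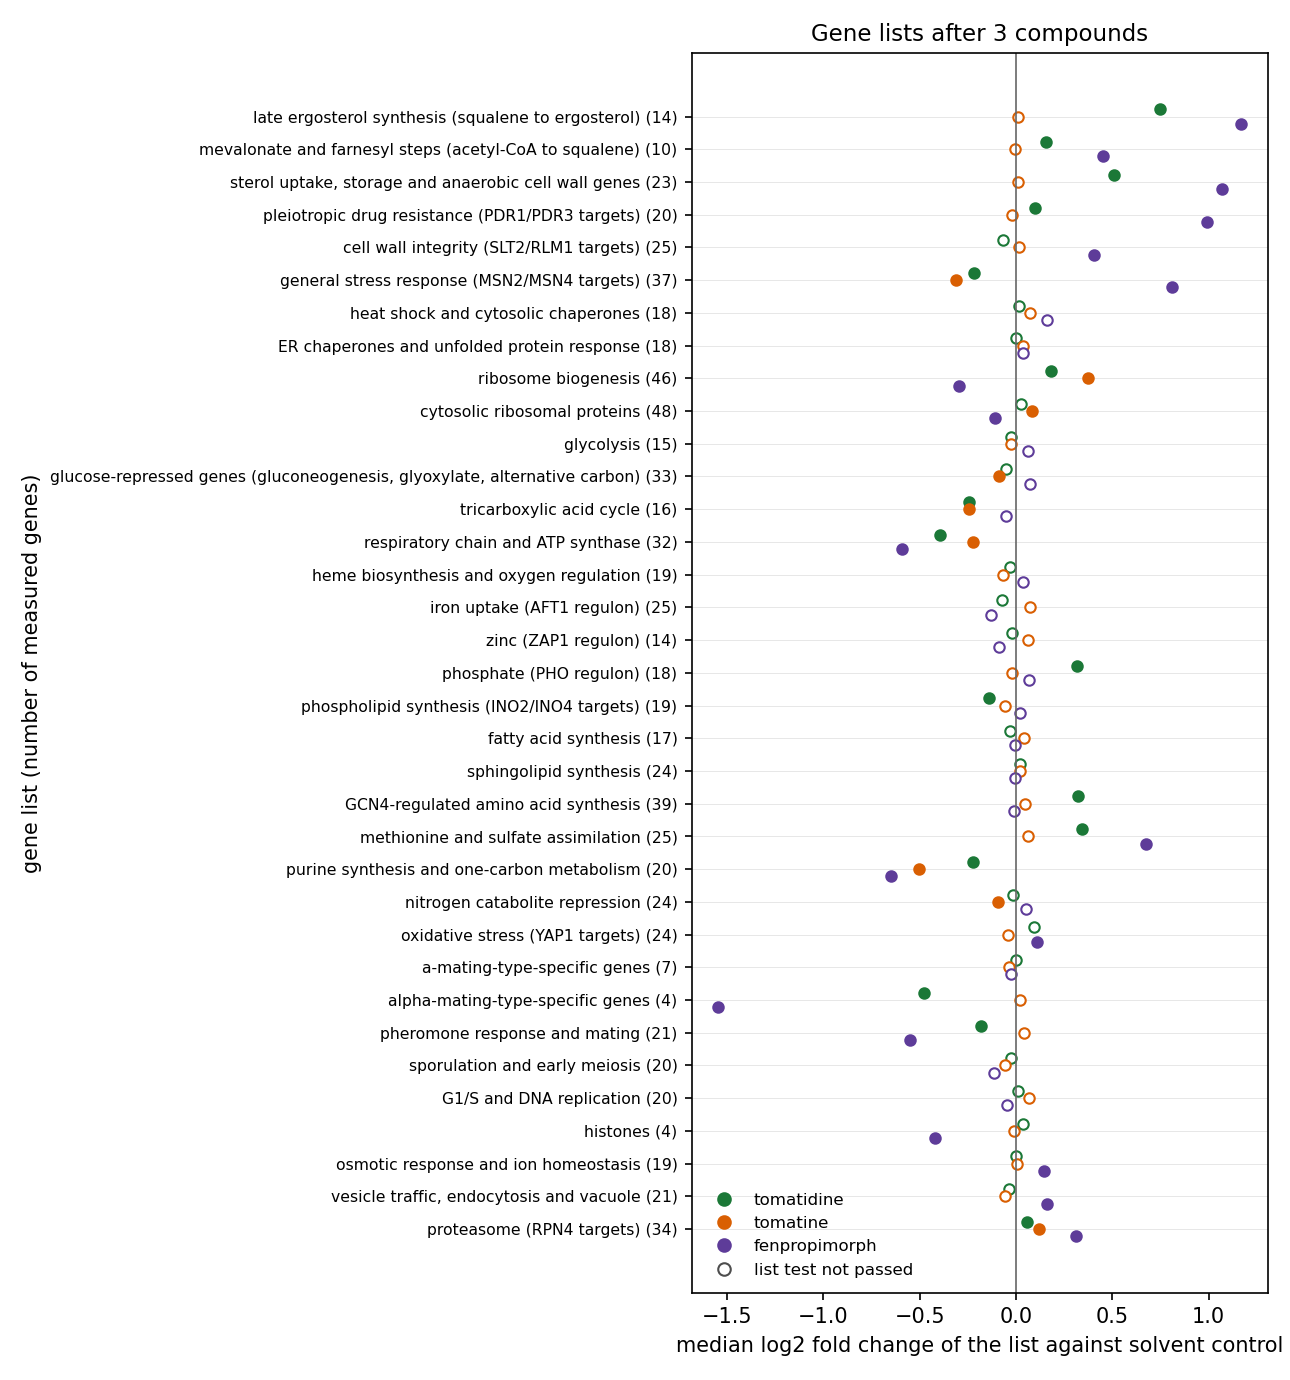
Median log2 fold change of each of the 35 gene lists against solvent control for the 3 compounds (filled points passed the camera test at the preset correlation, open points did not; the number of measured genes is in brackets). Late ergosterol synthesis lies at 0.75 for tomatidine, 0.01 for tomatine and 1.17 for fenpropimorph.

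Tomatine and tomatidine share the steroid and differ in the sugars that tomatine carries. The titles give the doses as 13.9 and 0.625 ppm, so in ppm they were not matched. Another label field gives 15 uM tomatidine for every sample and was not used, so the doses rest on the titles. Between the pair 472 probe sets differed, 204 higher and 268 lower with tomatine. This balance turned in 5 alternatives: 373 higher and 276 lower with dim probe sets left out, 353 and 311 with 16 added before the log, 284 and 267 with 1 probe set per gene, 268 and 257 with median centring, and 235 and 212 without moderation. All 14 late ergosterol genes were lower with tomatine than with tomatidine (14 adjusted over the list alone; median log2 fold change -0.72, camera adjusted p = 2.04e-25, adjusted p = 0.0167 with an estimated correlation): ERG3 2.05-fold (log2 fold change -1.03 ± 0.0626, adjusted p = 3.78e-06), ERG5 2-fold, ERG24 1.99-fold and ERG2 1.7-fold (log2 fold changes -0.9996 ± 0.0729, -0.9954 ± 0.148 and -0.77 ± 0.0707). DAN1, DAN4, PBI1, HES1 and TIR3 were the lowest, at -4.71 ± 0.344, -3.55 ± 0.196, -2.90 ± 0.18, -2.64 ± 0.215 and -2.24 ± 0.112. Of 23 genes of sterol uptake, storage and the anaerobic cell wall, 12 were lower (13 lower and 1 higher adjusted over the list alone). Across the full list the median log2 fold change was -0.50 (camera adjusted p = 3.93e-13, adjusted p = 0.0341 with an estimated correlation). No difference was called in UPC2 (-0.49, 95% interval -0.80 to -0.17, adjusted p = 0.0759), HMG1 (-0.07, 95% interval -0.23 to 0.09) or PDR5 (-0.18, 95% interval -0.53 to 0.17). The call of ERG6 was lost without tomatine 1 (adjusted p = 0.0837), tomatidine 1 (adjusted p = 0.113), tomatine 2 (adjusted p = 0.0922), tomatidine 2 (adjusted p = 0.0881), tomatine 3 (adjusted p = 0.0717) and tomatidine 3 (adjusted p = 0.0599).

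Phosphate genes were also lower with tomatine than with tomatidine, with 11 of 18 lower and 1 higher (12 and 1 adjusted over the list alone). For the whole list the median log2 fold change was -0.27 (camera adjusted p = 4.61e-14, adjusted p = 0.0722 with an estimated correlation). PHO89 was 4.03-fold and PHO5 3.23-fold lower (-2.01 ± 0.168 and -1.69 ± 0.113). Among the GCN4 targets 19 of 39 were lower (27 adjusted over the list alone; median log2 fold change -0.35, camera adjusted p = 1.44e-21, adjusted p = 0.103 with an estimated correlation), with ARG1 at -2.05 ± 0.3 and ARG4 at -1.06 ± 0.113. Of the methionine and sulfate genes 10 of 25 were lower (11 adjusted over the list alone). Over all its members the list had a median log2 fold change of -0.27 (camera adjusted p = 4.27e-10, adjusted p = 0.143 with an estimated correlation). Higher with tomatine were FET3, an iron oxidase of high-affinity uptake (1.12 ± 0.135), TIP1 (1.08 ± 0.111), NFG1 (1.06 ± 0.123), NDE1 (1.03 ± 0.167) and PRM7 (0.97 ± 0.172). Of the mating genes 7 of 21 were higher and 1 lower (11 and 1 adjusted over the list alone). At the list level the median log2 fold change was 0.23 (camera adjusted p = 1.55e-05, adjusted p = 0.103 with an estimated correlation). The count of 472 probe sets was 310 without tomatine 1, 261 without tomatidine 1, 303 without tomatine 2 and 261 with only these 2 groups in the fit. The count of 1 higher gene in the phosphate list was 0 without tomatine 1, 0 without tomatidine 1, 0 without tomatidine 2, 0 without tomatine 3 and 0 without tomatidine 3.

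The comparison of tomatidine with fenpropimorph sets the aglycone against a known sterol synthesis inhibitor, and 2831 probe sets differed, 1575 higher and 1256 lower with tomatidine. Of 14 late ergosterol genes, 10 were lower with tomatidine (11 lower and 1 higher adjusted over the list alone). The median log2 fold change of the whole list was -0.40 (camera adjusted p = 5.25e-05, adjusted p = 0.158 with an estimated correlation). ERG5 and ERG2 were lower (-0.51 ± 0.0729 and -0.50 ± 0.0707), while no difference was called in ERG3 (-0.14, 95% interval -0.27 to 0.00), ERG4 (0.15, 95% interval 0.01 to 0.28), ERG24 (-0.40, 95% interval -0.73 to -0.08) or ERG6 (-0.26, 95% interval -0.56 to 0.04). UPC2 was 2.67-fold lower (log2 fold change -1.42 ± 0.142, adjusted p = 1.72e-05). RTA1, MNC1, YPR145C-A, CPP3 and YPL088W were the lowest (-4.42 ± 0.0976, -4.11 ± 0.206, -4.01 ± 0.322, -3.37 ± 0.167 and -3.32 ± 0.147). The highest were ARG1 (2.81 ± 0.3), ARG3 (2.67 ± 0.345), WSC4 (1.79 ± 0.226), PDR12, a transporter of weak acids (1.46 ± 0.196), and PHO5 (1.37 ± 0.113).

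General stress genes were lower with tomatidine than with fenpropimorph, 32 of 37 (33 adjusted over the list alone; median log2 fold change -1.09, camera adjusted p = 7.6e-17, adjusted p = 0.158 with an estimated correlation), HSP12 by 7.81-fold (-2.97 ± 0.193). Cell wall integrity genes followed, with 16 of 25 lower and 2 higher (16 and 2 adjusted over the list alone; median log2 fold change -0.44, camera adjusted p = 5.7e-07, adjusted p = 0.158 with an estimated correlation), GSC2 by 6-fold (-2.58 ± 0.118). In contrast, 45 of 46 ribosome biogenesis genes were higher with tomatidine (46 adjusted over the list alone). Across the full list the median log2 fold change was 0.47 (camera adjusted p = 6.68e-13, adjusted p = 0.158 with an estimated correlation). Of 39 GCN4 targets, 30 were higher and 1 lower (31 and 2 adjusted over the list alone). For the whole list the median log2 fold change was 0.43 (camera adjusted p = 1.07e-07, adjusted p = 0.235 with an estimated correlation). The count of 2 higher genes in the cell wall integrity list was 1 without tomatidine 1, 1 without fenpropimorph 1, 1 without tomatidine 2, 1 without tomatidine 3 and 1 without fenpropimorph 3. The count of 1 lower gene in the GCN4-regulated amino acid synthesis list was 0 without tomatidine 2, 0 without tomatidine 3 and 0 without fenpropimorph 3.

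Tomatine and fenpropimorph, whose doses were not matched either, differed in 3555 probe sets, 2083 higher and 1472 lower with tomatine. At a change of at least 2-fold the balance was the opposite, with 61 higher and 335 lower. All 14 late ergosterol genes were lower with tomatine (14 adjusted over the list alone; median log2 fold change -1.17, camera adjusted p = 8.6e-12, adjusted p = 0.0835 with an estimated correlation), ERG5 by 2.84-fold, ERG24 by 2.64-fold and ERG2 by 2.4-fold (-1.51 ± 0.0729, -1.40 ± 0.148 and -1.26 ± 0.0707). UPC2 was 3.74-fold lower (log2 fold change -1.90 ± 0.142, adjusted p = 9.1e-07). YPR145C-A, DAN1, DAN4, PBI1 and HES1 were the lowest (-6.07 ± 0.322, -5.88 ± 0.344, -5.20 ± 0.196, -5.19 ± 0.18 and -4.59 ± 0.215), and SAG1, MF(ALPHA)2, TIP1, FET3 and NDE1 the highest (2.17 ± 0.118, 2.10 ± 0.11, 2.09 ± 0.111, 2.08 ± 0.135 and 1.97 ± 0.167). Ribosome biogenesis genes were higher with tomatine, 46 of 46 (46 adjusted over the list alone; median log2 fold change 0.71, camera adjusted p = 7.17e-15, adjusted p = 0.132 with an estimated correlation), and general stress genes lower, 34 of 37 (34 adjusted over the list alone). Over all its members the list had a median log2 fold change of -1.14 (camera adjusted p = 5.76e-16, adjusted p = 0.127 with an estimated correlation).

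Tomatidine and fenpropimorph shared 176 probe sets that were higher than control with both and 111 that were lower, where independent lists of these sizes would share 31.4 and 29.9. In 41 probe sets both compounds changed in opposite directions (expected 63.4). Across probe sets, which are not independent replicates, their log2 fold changes had r = 0.481. All comparisons with control use the same control arrays. In simulated data with no change, sharing these gave r of 0.50, and a covariance of 0.00658 against 0.0491 for tomatidine and fenpropimorph. At most 0 simulated probe sets were called in both. With no change simulated hardly any can be called in either comparison, so this count is no expectation for the shared probe sets. The 287 probe sets shared in direction were 184 without control 1 and 173 without tomatidine 2. The 41 in opposite directions were 15 without tomatidine 1, 13 without control 1, 11 without tomatidine 2, 23 without fenpropimorph 2, 16 without control 2, 25 without tomatidine 3 and 26 without control 3.

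Tomatine and fenpropimorph shared 17 higher and 47 lower probe sets (expected 32.1 and 27.7). Another 140 were higher with tomatine and lower with fenpropimorph, and 60 were the other way (expected 62.5 in all). Tomatidine and tomatine shared 26 higher and 36 lower probe sets (expected 6.08 and 3.13 for independent lists). Both comparisons use the same control arrays, so the lists are not independent. Their log2 fold changes had r = 0.403, where simulated data with no change gave 0.50, and a covariance of 0.0169 against 0.0066 simulated. The part of the shared probe sets due to the control arrays was not measured. With tomatine and fenpropimorph, the 64 shared in direction were 36 without tomatine 1, 19 without control 1, 26 without tomatine 2, 28 without control 2, 21 without tomatine 3 and 40 without control 3, and the 200 in opposite directions were 111, 30, 89, 38, 53 and 101 without the same arrays and 118 without fenpropimorph 2. With tomatidine and tomatine, the 62 shared in direction were 30 without tomatine 1, 33 without tomatidine 1, 11 without control 1, 28 without tomatine 2, 28 without tomatidine 2, 38 without fenpropimorph 2, 23 without control 2 and 16 without tomatine 3.

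**Figure D3:**
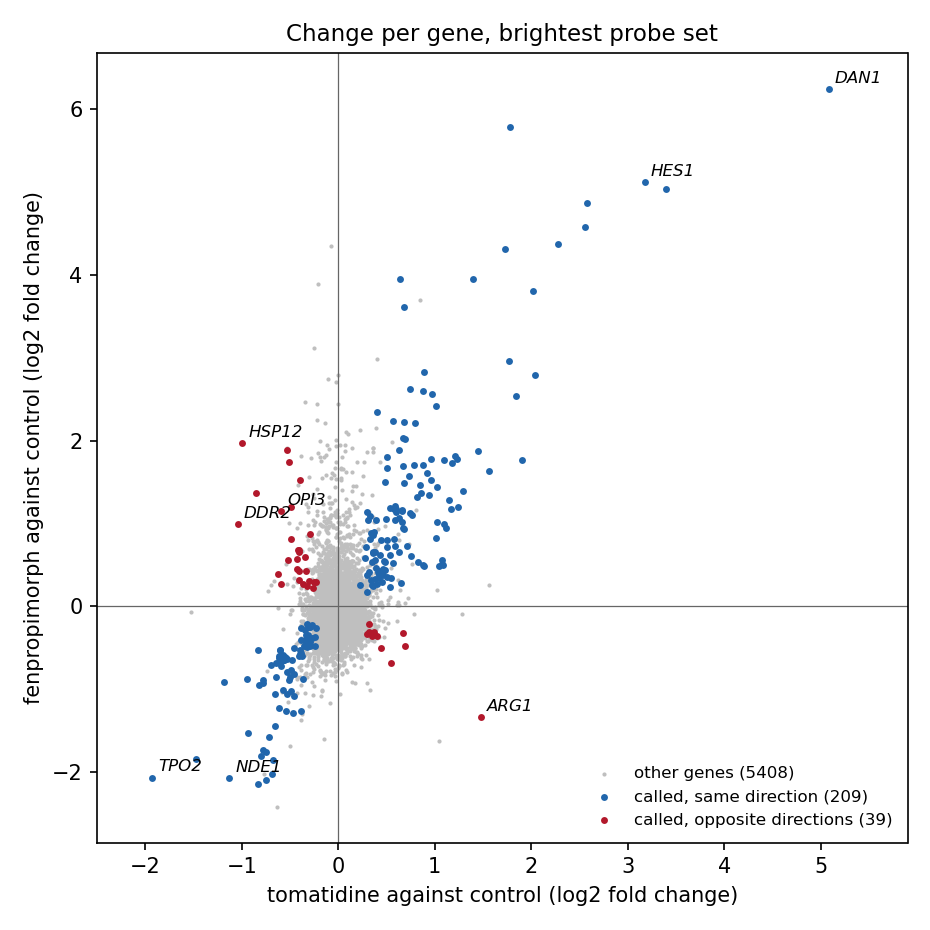
Log2 fold change against control with tomatidine (horizontal axis) and with fenpropimorph (vertical axis), 1 point per gene from its brightest probe set. In 209 genes both changed in the same direction and in 39 in opposite directions; DAN1 is at the upper right, and HSP12 and ARG1 lie on opposite sides.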

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

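No test in this part was chosen after the result was seen. The array's control probe sets take no part in the comparisons. One of the 60, for the 5′ part of SPT15, the TATA-binding protein, was higher with tomatidine than in the control arrays (log2 fold change 0.36, SE 0.0841, adjusted p = 0.0346 over the 60). Another, for RIP1, an iron-sulfur protein of complex III, was lower (-0.88, SE 0.157, adjusted p = 0.00727).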

How the results depend on the processing

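Adding 16 before the log and leaving out cross-hybridising probe sets were chosen after the data were seen; the other alternatives were planned. No called gene named by the rule turned direction under any alternative, and of the 7248 alternative values of the 431 called results 308 lost the call, in 60 results. The day block gave 372, 411, 2762, 463, 2758 and 3551 calls in the 6 comparisons in the order of the report. It ended no list call, but it ended 8 of the 431 called results. Among these were MSC1, IMP4 and FIG1 with tomatidine (limma adjusted p = 0.0628, 0.0802 and 0.0548). The report names none of the 8 as called, but MSC1 counts in its general stress list and IMP4 in its ribosome biogenesis list. With the block, 8 probe sets rose with tomatidine and fell with fenpropimorph and 21 did the reverse, against 12 and 29 without it. Calls gained with the block included ARG3 with tomatidine (adjusted p = 0.0375) and the heat shock list with fenpropimorph (adjusted p = 0.0355, against adjusted p = 0.329 with an estimated correlation and no block). With only the 2 compared groups in the fit, the counts for tomatidine, tomatine and tomatine against tomatidine were 252, 121 and 261; fewer arrays give less information on the spread. A change of at least 2-fold left 53, 13, 335, 47, 280 and 396 probe sets, and 2, 37 and 4 shared in direction by tomatidine and tomatine, tomatidine and fenpropimorph, and tomatine and fenpropimorph. The balance of higher and lower calls turned for tomatine against tomatidine as the report states, for tomatine against control with only these 2 groups (56 higher, 65 lower), without control 2 (42 and 57) and without tomatine 3 (46 and 54), and at 2-fold for tomatine and fenpropimorph against control as the report states and for tomatidine and tomatine against fenpropimorph (32 and 248, 61 and 335); the cause was not tested. Tomatine against control had 645 calls with 1 probe set per gene and 625 with 16 added; the cause was not tested. An estimated correlation, which allows for genes that vary together, ended most list calls. In the 6 comparisons 2, 0, 0, 2, 0 and 0 calls held. For the 3 pairs of compounds, camera had called 5 lists higher and 11 lower, 7 and 14, and 6 and 17. The calls that held were those of the late ergosterol and the sterol uptake lists, with tomatidine and for tomatine against tomatidine. The calls that ended included the mevalonate list with tomatidine (adjusted p = 0.119). They also included the late ergosterol and mevalonate lists with fenpropimorph (0.0686 and 0.0882). The uncalled ergosterol lists with tomatine turned sign under fry (adjusted p = 0.984 and 0.882), the late list also without control 2 (0.961) and the mevalonate list without control 1 and tomatine 2 (0.986 and 0.916); the cause was not tested. Without 1 array the counts ranged from 221 to 339 (tomatidine), 83 to 276 (tomatine), 2135 to 2637 (fenpropimorph), 261 to 367, 2164 to 2662 and 2952 to 3347 (the pairs), and 2643 to 3383 for any difference. Each of these fits had 1 array fewer, which does not account for the range among them. With tomatine the count was 83 without control 1 and 276 without control 3, and the cause was not tested. The late ergosterol and mevalonate lists with tomatine ranged over adjusted p = 0.523 to 0.986 and 0.846 to 0.986.

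Some uncalled log2 fold changes turned sign, and the cause was not tested. With tomatine ERG27 was -0.0081 under quantile normalization, ERG10 0.0104 and ERG13 0.0161 under median centring, and ERG9 -3e-04 with array weights. Without 1 array the tomatine values ranged from -0.0495 to 0.0564 for ERG27, -0.047 to 0.0207 for ERG10, -0.0536 to 0.0456 for ERG13, -0.052 to 0.064 for ERG9, -0.0741 to 0.007 for ERG11, -0.1153 to 0.0141 for ERG20, -0.1743 to 0.1709 for ERG24, -0.0182 to 0.0497 for NCP1, -0.5534 to 0.1171 for PRE5 (-0.3248 with all arrays) and -0.2062 to 0.0422 for ERG1 (-0.1133). PDR5 ranged from -0.2529 to 0.0712 with tomatidine, -0.3122 to 0.0074 for tomatine against tomatidine (-0.1822 with all arrays) and -0.1015 to 0.2181 for tomatidine against fenpropimorph; its signal was under the lower quartile, where background limits what can be seen.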

Other observations

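Apart from the correlation that leaves out shared arrays, the tests of explanations and of other splits in this part were chosen after the result was seen, and the genes of the next paragraph were chosen after their values were seen. The comparison with genes of like signal was chosen after its pattern was seen, with its bound written before its value was computed.

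Some genes moved in opposite directions with tomatidine and with fenpropimorph. The stress genes DDR2 and HSP12 fell with tomatidine (log2 fold changes -1.04 and -0.9954) and rose with fenpropimorph (0.99 and 1.97). OPI3, a methyltransferase of phosphatidylcholine synthesis, fell with tomatidine (-0.60, adjusted p = 0.00396) and rose with fenpropimorph (1.15, adjusted p = 2.98e-06). ARG1, of arginine synthesis, and LYS20, of lysine synthesis, rose with tomatidine (1.47 and 0.67) and fell with fenpropimorph (-1.34 and -0.32). PHM6, a gene of the phosphate regulon, did the same (0.69 and -0.48). The tomatidine call of HSP12 was lost without tomatidine 1 (adjusted p = 0.0562), and that of ARG1 without tomatidine 1 (adjusted p = 0.0677) and tomatidine 3 (adjusted p = 0.0548).

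With fenpropimorph, of 21 genes of vesicle traffic, endocytosis and the vacuole, 8 rose (9 adjusted over the list alone; median log2 fold change 0.16, camera adjusted p = 0.000522, adjusted p = 0.156 with an estimated correlation), with the vacuolar protease genes PRB1 at 1.89 and PEP4 at 0.56; the count was 5 without control 3.

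The changes with tomatidine and with fenpropimorph had r = 0.481 over probe sets. This value alone does not show that they ran together, since shared control arrays gave 0.50 in simulated data with no change. Tomatidine minus control against fenpropimorph minus tomatine, which share no array, still gave r = 0.29, which argues against shared control arrays as the whole cause. A single response of different strength would leave no more probe sets called in opposite directions than false calls allow. There were 41, where 20.6 false calls were allowed among the tomatidine calls. That allowance is an average, and genes that vary together can pass it at once. Without tomatidine 2 these were 11 with 11 allowed. The margin was also narrow without control 1 (13 with 12.2 allowed), tomatidine 1 (15 with 13) and control 2 (16 with 13.6). At a tomatidine adjusted p under 0.01, a cut outside the criterion written for this test, the opposite probe sets were 9 with 1.89 allowed. They were 4 to 11 with 0.98 to 1.81 allowed when each array was left out. The counts go against a single response but do not exclude it. A shared response to altered sterols, beside responses of each compound alone, may account for both values, and it was not tested.

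With fenpropimorph, 16 of 21 mating genes were lower and 1 higher (17 and 1 adjusted over the list alone; adjusted p = 0.0882 with an estimated correlation). Cells of the a type in the culture are argued against by the genes specific to a cells, whose median log2 fold change was -0.0284 where a rise was needed. A smaller share of alpha cells would lower the 4 genes specific to alpha cells alike if their probe sets respond alike, which was not tested. The highest and lowest of them were apart by 1.4935 on the log2 scale (SE 0.128, which covers only the spread between arrays). Lower expression within alpha cells may account for the pattern and was not tested.

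With tomatine, 27 of 46 ribosome biogenesis genes were higher and 13 of 37 general stress genes lower (45 and 19 adjusted over the list alone; as few as 3 and 3 without 1 array; adjusted p = 0.263 and adjusted p = 0.402 with an estimated correlation). The medians of the 2 lists lay 0.6804 apart on the log2 scale, while those of other genes of like signal lay 0.0095 apart (95% of draws from -0.062 to 0.0823). This argues against array scaling that depends on the signal within the deposited values. These had already passed through RMA, so the comparison could not see scaling before it. Less use of glucose by the treated culture cannot be told apart from a direct effect of tomatine. The list of glucose-repressed genes was lower by camera, as less use of glucose would need (adjusted p = 0.0157, adjusted p = 0.486 with an estimated correlation; adjusted p = 0.103 without tomatine 1 and 0.0632 without control 2). By fry it was lower with adjusted p = 0.207, and the arrays do not measure growth. The ribosome biogenesis and general stress lists were also called by camera with tomatidine, which was compared with the same control arrays. No test was run of what these shared arrays add to the pattern.

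For the comparisons of 3 arrays with 3 there are 10 splits, so a share under 0.05 cannot be reached. The real split was the 1 split with as many calls in each of the 6 comparisons: 412, 404, 2808, 472, 2831 and 3555. The highest other split gave 1 for tomatidine, 0 for tomatine, 1 for fenpropimorph, 1 for tomatine against tomatidine and 0 for each of the other pairs. Among splits that part 3 day pairs, as the real one does, the highest other was 0, except 1 for tomatine against tomatidine. For any difference among the 4 groups, 1 of 100 splits, the real one, reached 3446, so chance alone is an unlikely source of that count. The draws did not keep the days paired. The highest other, 2310, and another with 2016 kept the 3 fenpropimorph arrays in one group, and the remaining splits gave at most 4. The count therefore rests largely on fenpropimorph, and this test gives no separate evidence on tomatidine or tomatine. The test of day called 0 probe sets by limma (579 at an unadjusted p under 0.05), so 100 of 100 shuffles of the day give as many whatever they hold, and they say nothing on the day (highest other 1).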
